A study of Arabidopsis thaliana with 8 samples.

How the data were processed

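URI ChIP-seq was analysed from roots of Arabidopsis thaliana kept for 72 h with sufficient or deficient Fe. The 8 libraries were grouped by their titles into 3 URI ChIP libraries and 1 IgG control for each Fe condition. Per the submitters' processing notes, Trimmomatic 0.33, Bowtie 1.2.2, SAMtools 1.3.1, Picard 2.4.1, bedtools 2.26.0, MACS2 and DiffBind were used with the TAIR10 genome. Their settings, the versions of MACS2 and DiffBind, the normalisation between libraries, the use of the IgG libraries in calling or counting and whether peaks were called per library or on pooled libraries are not given in the sources used here.

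The values came from 1 table of 2366 peaks that the authors deposited. Its headers name a concentration, a concentration for each Fe condition and a fold, without a scale or unit. The concentrations were read here as log2 values of normalised reads, averaged over all URI libraries or over those of a condition. The fold was read as a log2 change. Taken as log2, the first concentration equals the log2 of the mean over both conditions within 0.0093. The deposited fold equals sufficiency minus deficiency within 0.01, so its sign was reversed here to give deficiency minus sufficiency. Reads in the text are 2 to the power of the deposited concentration. The deposited p-value and FDR columns are the authors' own, and the test behind the p-value is not given in the sources used here. The deposited FDR matched a Benjamini-Hochberg adjustment over 1311 peaks, with a largest relative difference of 0.489%, and was 1 for the other 1055 peaks, whose mean concentration was at most 3.52 (11.5 reads). Peaks were 305 to 5342 bp wide (median 734), and mean concentrations ranged from 1.82 to 8.38 (median 3.61, or 12.2 reads). Wider peaks held more reads (Spearman rho of 0.90 across peaks, which are not independent replicates), so a concentration is not a density. Peak coordinates are printed as deposited, and whether starts count from 0 or 1 is not given in the sources used here.

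The table holds no value per library, so no model was fitted to libraries and the depth per library is unknown. Differential binding was read from the deposited FDR, with a threshold of 0.05. As a check of scaling, each change was recentred on the median peak, and its p-value was recomputed from the standard error that the deposited p-value implies under a normal approximation. For changes under 0.2 (log2), that error was the median over 101 peaks of like concentration. Adjustment again covered the 1311 peaks.

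Gene positions and symbols came from an NCBI RefSeq gene table (assembly GCF_000001735.4, TAIR10.1), used for names and for which genes lie near a peak. On 4 of the 5 chromosomes the share of peak midpoints inside genes was lowest with no shift between peaks and genes, and on chromosome 2 it was equally low at a shift of -100 bp (22.3%). A gene counted as near a peak when the gene widened by 1500 bp on both sides overlapped a peak by at least 1 bp. The planned windows around transcription start sites needed a strand, which the table lacks, so gene ends were used on both sides. The planned tests for the G-box motif needed a genome sequence and were not run. Peaks within 1500 bp of a list gene were named by that gene, and other peaks by the nearest of 27444 protein-coding genes to their midpoint.

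The 12 gene lists with 149 genes, the tests, the thresholds and the rule for named genes were fixed before the data were examined. The rule names every gene of the 4 Fe lists with a peak, the 10 peaks of highest concentration, the 10 largest increases and decreases at an FDR under 0.05, and up to 4 members of each other list. Genes outside it were chosen after their values were seen. These were the rising peaks beyond the 10 largest that are near no gene of the Fe lists, AT1G13609 and the other neighbouring genes given beside a peak's name, TAPX and SUFE1 of the plastid list, the list genes named as having no peak, and all genes of the further observations outside the lists. Genes near a peak were tested with Fisher's exact test (one-sided) against all other protein-coding genes. Changes of a list were tested as the median over its peaks against 10000 random sets, each peak replaced by 1 of the 50 nearest in concentration (two-sided permutation test). Positions were tested against 1000 circular shifts. List tests were adjusted by Benjamini-Hochberg. The test of rising peaks near Fe genes, the recentring, the matching on flanking space and the tests of the further observations were chosen after the data were seen. Alternatives covered the FDR threshold, the adjustment, windows of 1000 bp and 3000 bp, the midpoint in place of an overlap, the nearest gene, matching and the mean in place of the median.

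The list tests, the recentring and the overlap of genes and peaks were tested on simulated data. The list test of changes called 4% of random sets of 8 peaks and 100% of sets raised by 1 (log2) among the 2366 peaks. Those simulated changes had the same centre and normal spread at every concentration, so the matching on concentration was not tested. The recentring recovered 31% of peaks raised by 1 and 93% of those raised by 2 among 1311 peaks, and called 7 of 1111 unchanged ones. The planted offset of -0.46 (log2) was recovered as -0.4. The simulated p-values came from the same normal approximation, so whether the deposited p-values follow it was not tested. The list test of nearby genes called 1% of random lists of 14 genes. It called 100% of lists with 8 of 14 planted, but each such list gives the same counts, so that outcome was fixed in advance. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.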

Results

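URI, also called bHLH121, is a basic helix-loop-helix transcription factor of the Arabidopsis thaliana response to low iron (Fe). Its binding along the chromosomes was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in roots of a line in which the uri mutant is complemented. Roots were kept for 72 h with sufficient or with deficient Fe. The series holds 8 libraries, namely 3 URI ChIP libraries and 1 IgG control library for each Fe condition. The authors' deposited table lists 2366 peaks, with 1 mean concentration (log2 of normalised reads) per Fe condition, a log2 change, a p-value and a false discovery rate (FDR). These group means come without the spread between replicates, so the error behind each change is given by its deposited p-value and FDR. The depth of each library is unknown, and the sample descriptions do not say whether the 3 libraries of a condition came from separate plantings, so the p-values may measure technical spread. All changes below are Fe deficiency minus Fe sufficiency, so a positive log2 value is higher URI signal under deficiency.

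The first question was where URI was found in roots. Ferritin genes, which encode the plastid Fe storage protein, carried some of the strongest peaks: in the authors' deposited table FER3 (AT3G56090, chromosome 3, 20814350 to 20817890) had 265 normalised reads with sufficient Fe and 139 under deficiency, and FER1 (AT5G01600) had 251 and 150.1. The strongest peak of the authors' deposited table lay beside DGAT3 (AT1G48300, a diacylglycerol acyltransferase, chromosome 1, 17845339 to 17847777), with 402 reads with sufficient Fe and 263 under deficiency. The POPEYE gene PYE (AT3G47640), which encodes a bHLH repressor of Fe homeostasis genes, and NAC047 (AT3G04070), which encodes a NAC transcription factor, were also among the 10 strongest, with mean concentrations of 7.16 and 7.24 in the authors' deposited table. The other peaks of these 10 in the authors' deposited table were nearest to AT3G56360 (7.83), AT1G78070 (7.35), AT5G05250 (7.12), AT3G17770 (6.74) and AT5G61997 (6.74). None of these 10 peaks passed an FDR of 0.05 between the Fe conditions in the authors' deposited table. Before adjustment, p-values in the authors' deposited table were under 0.05 for FER3 (log2 change -0.93, p = 0.0298), PYE (0.66, p = 0.0291), AT5G05250 (0.68, p = 0.0282) and AT3G17770 (0.70, p = 0.0164).

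Peaks lay mostly next to genes. The midpoints of 1387 of the 2366 peaks (58.6%) were outside protein-coding genes but within 1000 bp of one, against 20.4% ± 0.979 (SD over 1000 circular shifts of the peaks along their chromosomes). The one-sided permutation p was 0.000999, the smallest that 1000 shifts can give. Only 460 midpoints (19.4%) lay inside a protein-coding gene, against 54.2% ± 3.09 (SD) after shifting. The annotation table used here gives no strand, so promoters and gene ends are not told apart.

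Genes of Fe homeostasis were near URI peaks far more often than other genes. A peak lay within 1500 bp of 8 of 14 Fe-deficiency transcription factor genes, 5 of 6 genes for Fe-deficiency E3 ligases and peptides, 7 of 11 Fe uptake and coumarin genes and 15 of 27 Fe transport and storage genes, while 11.8% of other protein-coding genes had one. The adjusted p-values of Fisher's exact test (one-sided, Benjamini-Hochberg over 12 lists) were 0.000275, 0.000375, 0.000275 and 6.20e-07. Among the transcription factors, the Ib bHLH genes bHLH38, bHLH39, bHLH100 and bHLH101 had peaks, as did PYE, bHLH11, MYB10 and MYB72, whereas FIT, ILR3, bHLH34, bHLH104, bHLH115 and URI itself had none within 1500 bp in the authors' deposited table. Of the E3 ligases and peptides, BTS, BTSL1, IMA1, IMA2 and IMA3 had a peak and BTSL2 had none. In the uptake and coumarin list, IRT1 and IRT2 (Fe transporters, sharing 1 peak) and FRO2 and FRO3 (ferric reductases) had a peak. So did AHA2 (a proton pump), AT3G13610 (coumarin synthesis) and PDR9 (coumarin export). In the transport and storage list, peaks lay within 1500 bp of NAS3, OPT3, YSL3, NRAMP1, NRAMP4, NRAMP6, VTL1, VTL2, VTL5, ZIF1, FPN1, NEET, FER1, FER3 and FER4. The peaks given for MYB72, IRT2, FRO2, AT3G13610, NAS3, NRAMP6 and FPN1 did not overlap those genes, nor did the stronger peaks of NRAMP1 and VTL1. For FRO2, NRAMP6, FPN1 and the stronger NRAMP1 peak, the midpoint lay inside another gene.

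Genes outside the Fe lists were near peaks too, and 4 of the 8 other lists passed the test. Of 9 plastid Fe-S and tetrapyrrole genes, 6 had a peak (Fisher's exact test, adjusted p = 0.000399), among them HEMA1, an early enzyme of tetrapyrrole synthesis, FD2, a ferredoxin, CGLD27 and SAPX. So did 6 of 12 circadian clock genes (PRR5, GI, PRR9 and LUX among them, adjusted p = 0.00267), 5 of 12 jasmonate genes (JAZ1, JAZ3, MYC2 and JAZ6 among them, adjusted p = 0.0134) and 7 of 18 highly expressed housekeeping genes (ACT2, UBQ10, GAPC2 and PIP1A among them, adjusted p = 0.00536), each by Fisher's exact test. The lists for copper and zinc deficiency (3 of 9 genes, ZIP5, ZIP3 and FRO5, adjusted p = 0.107), phosphate starvation (3 of 13, SPX1, PHT1;1 and PLDZ2, adjusted p = 0.231), light signalling (2 of 10, ATHB2 and PIL1, adjusted p = 0.365) and root hairs (0 of 8, adjusted p = 1) did not pass Fisher's exact test. When only the peaks with an FDR under 0.05 were kept, the plastid, clock, jasmonate and housekeeping lists had 0 genes near a peak, while all 4 Fe lists still passed. The shares of different lists were not tested against each other here, apart from the Fe lists against housekeeping genes, described among the further observations.

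The second question was how URI binding differed between Fe-deficient and Fe-sufficient roots. URI signal was higher under Fe deficiency at 26 peaks and lower at 1 at an FDR under 0.05 in the authors' deposited table, out of 1311 peaks whose FDR was adjusted there. IRT1, the main root Fe transporter, had the smallest p-value of the authors' deposited table, with 29.7 reads with sufficient Fe and 133 under deficiency (chromosome 4, 10705482 to 10707512, log2 change 2.15, FDR 4.24e-11). The peak at bHLH38 and bHLH39 rose 3.92-fold in the authors' deposited table, from 34.3 to 135 reads (FDR 1.63e-09), bHLH100 rose from 21.3 to 92.4 (FDR 2.37e-08), and IMA3, a small peptide that promotes Fe uptake, from 30.3 to 119 (FDR 2.37e-08). BTS, an E3 ligase that limits the Fe response, rose 3.10-fold in the authors' deposited table, from 44.9 to 139 reads (FDR 7.58e-07). Over the 26 rising peaks, changes ranged from 2.23-fold to 9.38-fold, with a median of 3.48-fold.

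By size of change, the rising peaks of the authors' deposited table were led by AT1G13610 (log2 change 3.23, from 2.36 to 22.3 reads, FDR 0.0371), AT3G55860 (2.95, FDR 0.0014) and NRAMP4 (2.56, from 8.63 to 50.9 reads, FDR 2.94e-06), a vacuolar Fe exporter. The peak named for AT1G13610 also overlaps AT1G13609, and its FDR over all 2366 peaks would be 0.0646. Next in the authors' deposited table came AT2G14247 (2.32, FDR 4.39e-08), the peak nearest to IGMT5 with VTL2 within 3000 bp (2.23, FDR 7.58e-07), AT5G53420 (2.19, FDR 0.0194), IRT1, bHLH100, CDI (2.08, FDR 7.23e-05) and AT3G01345 (1.99, FDR 0.000708). Smaller rises in the authors' deposited table included OPT3 (log2 1.66, FDR 8.21e-07), which moves Fe in the phloem, a peak nearest to NAS4 (1.68, FDR 7.58e-07), a nicotianamine synthase gene, BTSL1 (1.37, FDR 1.62e-05), ZIF1 (1.32, FDR 0.000708), a vacuolar nicotianamine transporter, a second peak at bHLH39 (1.3, FDR 0.000265) and FRO3 (1.24, FDR 0.0094). The peak given for IMA3 has its midpoint inside AT2G30760, and that given for BTSL1 lies nearest to AT1G74780. The remaining rises in the authors' deposited table lay at AT3G27590 (log2 1.83, FDR 0.00148), RPL16A (1.77, FDR 0.000311), a ribosomal protein gene, AT5G25840 (1.77, FDR 0.000233), AT5G51010 (1.74, FDR 0.0145), AT3G08490 (1.70, FDR 0.000233), with FRD3 within 3000 bp, TSO2 (1.63, FDR 0.000708), a ribonucleotide reductase subunit, and AT3G43660 (1.16, FDR 0.0145). The single decrease in the authors' deposited table lay beside the aquaporin gene PIP2A (AT3G53420, chromosome 3, 19805816 to 19806596), from 19.3 to 5.66 reads (log2 change -1.77, FDR 0.0284).

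Most peaks leaned the other way from the called ones. The median log2 change of all 2366 peaks in the authors' deposited table was -0.46, with 1889 peaks (79.8%) lower under deficiency and 470 higher. Relative to this median peak, with the standard error implied by each deposited p-value, 63 peaks were higher at an FDR under 0.05 and 0 were lower. All 26 rising peaks were among these 63, at relative changes of 2.61 for IRT1, 2.09 for BTS and 1.70 for FRO3 (log2), while PIP2A at -1.31 no longer passed (FDR 0.157). Of the 37 peaks added, 4 were near genes of the Fe lists, namely bHLH101, MYB10, MYB72 and PYE. From the 10 strongest peaks, those at PYE (FDR 0.00665), AT5G05250 (FDR 0.00698) and AT3G17770 (FDR 0.0028) were thus added as higher under deficiency.

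**Figure D1:**
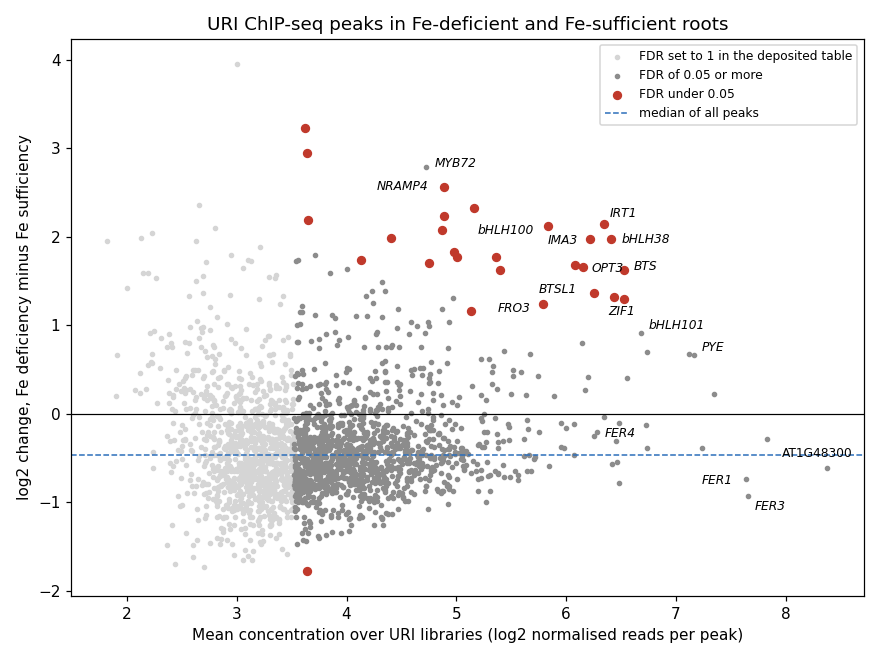
Each point is 1 of the 2366 URI peaks; the horizontal axis gives its mean concentration over the URI libraries (log2 normalised reads) and the vertical axis its log2 change, Fe deficiency minus Fe sufficiency, from the authors' deposited table. Red points have an FDR under 0.05 (26 above 0 and 1 below), and the dashed line is the median of all peaks, -0.46; FER1 and FER3 lie below that line and FER4 lies below 0 but above it.

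The 26 rising peaks were more often near genes of Fe homeostasis than other peaks were. Of them, 11 (42.3%) lay within 1500 bp of a gene of the 4 Fe lists, against 15 of the 1285 other adjusted peaks (1.17%), and Fisher's exact test (two-sided) gave p = 1.08e-13. The peaks of the Fe-deficiency transcription factors were higher under deficiency as a group: their median log2 change was 1.40 over 8 peaks, against -0.20 in random peaks of matched concentration (permutation test, adjusted p = 0.0066). Of these 8 peaks, 3 passed an FDR of 0.05 in the authors' deposited table and 7 passed when adjusted over the list alone. The members that did not pass in the authors' deposited table had changes of 2.79 for MYB72 (FDR 0.0689), 1.49 for MYB10 (FDR 0.0657), 0.91 for bHLH101 (FDR 0.0923), 0.66 for PYE (FDR 0.247) and 0.68 for bHLH11 (FDR 1). The E3 ligase and peptide list had a median of 1.74 over 5 peaks, against -0.13 in matched peaks (permutation test, adjusted p = 0.0137), with 3 peaks past the FDR of 0.05 and 5 adjusted over the list alone. In the authors' deposited table, IMA1 had a change of 2.36 (p = 0.000808) and the strongest peak at IMA2 one of 1.74 (p = 0.00724), but both FDR values were set to 1 at these low concentrations.

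Genes of the Fe uptake and coumarin list were split. The peak shared by IRT1 and IRT2 and that of FRO3 rose, whereas in the authors' deposited table FRO2 had a log2 change of 0.54 (FDR 0.393), PDR9 -0.27 (FDR 0.653), AHA2 -0.61 (FDR 0.376) and AT3G13610 -0.64 (FDR 1). Relative to the median peak the sign of PDR9 turned, to 0.19. The peaks given for FRO2 and AT3G13610 lay near those genes without overlapping them. The list median of 0.135 over 6 peaks did not differ from matched peaks (permutation test, adjusted p = 0.211), and 2 peaks passed both the deposited FDR and the test adjusted over the list alone. Against peaks not matched on concentration it passed (permutation test, adjusted p = 0.0407). With a window of 1000 bp the median was 0.54 and fell just short of passing (permutation test, adjusted p = 0.0502). The mean, 0.402, did not pass either (permutation test, adjusted p = 0.114).

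Transport and storage genes ranged from NRAMP4 at 2.56 to NRAMP6 at -1.09. The peak given for NRAMP6 was weak, from 10.6 to 4.99 reads in the authors' deposited table (p = 0.0578), and did not overlap that gene. Of 17 peaks, OPT3, NRAMP4 and ZIF1 rose, with 3 also adjusted over the list alone. Below the threshold, values in the authors' deposited table were 1.59 for NEET, 1.0 for VTL2, 0.35 for VTL1, 0.33 for VTL5, 0.19 for YSL3, 0.17 for NRAMP1, -0.17 for NAS3 and -0.47 for FPN1. The peaks of NEET, VTL5, NRAMP1, FPN1 and NRAMP6 were among those of low concentration left out of the deposited FDR adjustment. NRAMP1 and VTL1 each had a further, weaker peak in the authors' deposited table, with a change of -0.98 (p = 0.0723) at the one that overlaps NRAMP1 and 0.60 (p = 0.145) at VTL1. The ferritin peaks had changes of -0.93 for FER3 (FDR 0.247), -0.74 for FER1 (FDR 0.327) and -0.21 for FER4 (FDR 0.649) in the authors' deposited table. Relative to the median peak these were -0.47, -0.28 and 0.25, so the sign of FER4 turned, as did that of NAS3 (0.29). The list median of 0.19 lay above the -0.31 of matched peaks (permutation test, adjusted p = 0.0401), a call that was lost with the mean in place of the median (adjusted p = 0.0528), with 1 peak per gene (adjusted p = 0.106) and with a window of 1000 bp (adjusted p = 0.0502).

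The plastid Fe-S and tetrapyrrole list had a median change of 0.36 over 7 peaks, against -0.46 in matched peaks (permutation test, adjusted p = 0.0158). No single peak of it passed an FDR of 0.05 in the authors' deposited table, and 2 passed adjusted over the list alone; values there were 1.18 for FD2 (FDR 0.0991), 1.04 for CGLD27 (FDR 0.183), 0.62 for HEMA1 (FDR 0.317) and 0.36 for SAPX (FDR 0.547). Of the 7 peaks 2 had values below 0 in the authors' deposited table, TAPX at -0.44 and SUFE1 at -0.24, and both signs turned relative to the median peak (0.02 and 0.22). Relative to the median peak, FD2 (FDR 0.00154), CGLD27 (FDR 0.00682) and HEMA1 (FDR 0.0292) passed. The other lists did not differ from matched peaks. Their medians were -0.13 for copper and zinc deficiency (adjusted p = 0.369), -0.51 for phosphate starvation (adjusted p = 1), -0.64 for the clock (adjusted p = 0.378), -0.16 for jasmonate (adjusted p = 0.378) and -0.60 for housekeeping genes (adjusted p = 0.559), all in permutation tests, and the 2 light signalling peaks had a median of -0.265 (adjusted p = 0.559). Relative to the median peak, the copper and zinc, jasmonate and light signalling medians lay above 0. None of their peaks had a deposited FDR under 0.05, and adjusted over the list alone the only one to pass was ZIP3, with a log2 change of -1.36 (p = 0.0148) in the authors' deposited table, which relative to the median peak was -0.90 (p = 0.107).

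**Figure D2:**
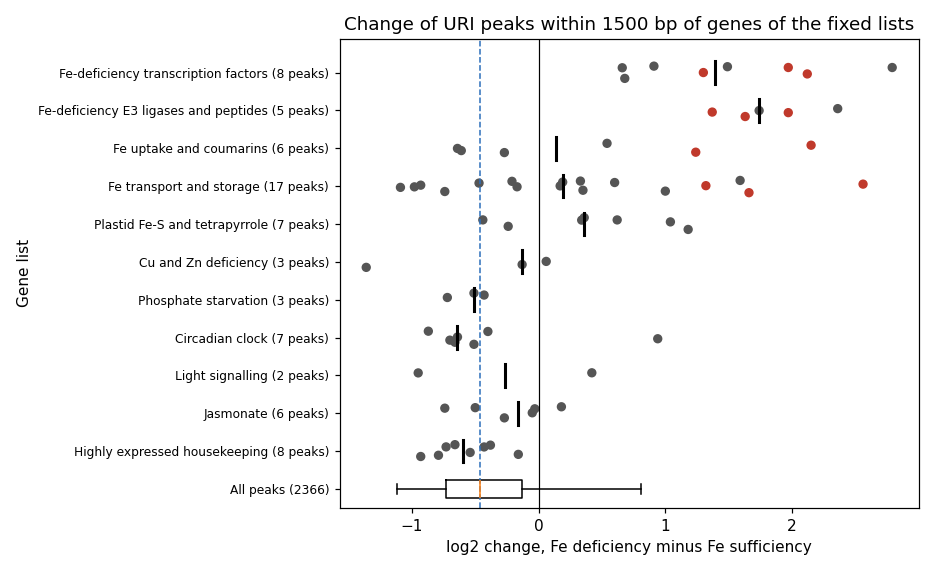
Each point is a URI peak within 1500 bp of a gene of the list named on the vertical axis, placed by its log2 change, Fe deficiency minus Fe sufficiency, in the authors' deposited table; red points have an FDR under 0.05, black bars are list medians, and the box of all peaks spans the quartiles with whiskers from the 5th to the 95th percentile. The dashed line is the median of all peaks (-0.46), and the medians of the transcription factor list (1.40) and the E3 ligase and peptide list (1.74) lie farthest to its right.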

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

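The recentring, the matching on flanking space and the test of rising peaks near Fe genes, with its windows, were chosen after the data were seen. Of 146 alternative values over 27 results, 134 were counted as the same. For peak counts this meant a count of similar size, and for tests the same side of the threshold. Lists that passed neither in the main setting nor in the alternative are included. Recentring on the median peak gave 63 peaks higher and 0 lower in place of 26 and 1, because it moves every change up by 0.46 (log2). An FDR of 0.01 left 22 higher and 0 lower, and 0.1 gave 34 and 6. Adjusting over all peaks also gave 26 and 1, with 26 of its 27 peaks shared with the authors' calls; it lost AT1G13610 and gained AT5G22120. With only the peaks at an FDR under 0.05, the plastid, clock, jasmonate and housekeeping lists each had 0 genes near a peak (Fisher's exact test, adjusted p = 1), since none of their peaks passed. The uptake list median of 0.135 passed without matching (permutation test, adjusted p = 0.0407). The transport and storage list lost its call in the permutation test with 1 peak per gene (0.19, adjusted p = 0.106), with the mean (0.305, adjusted p = 0.0528) and with a window of 1000 bp (0.18, adjusted p = 0.0502), where its value hardly moved. No paired analysis was possible because the table has no value per library, and for the same reason no library could be left out and no other split of the libraries could be counted. The G-box tests and their alternatives were not run, nor were the pseudocounts, filters and fits that need library values. What depth limits was not tested, since the depth per library is unknown. The FDR was set to 1 for 1055 peaks with at most 11.5 reads, IMA1, IMA2 and NEET among them, which did not pass when adjusted over all peaks either (FDR 0.0659, 0.241 and 0.349).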

Other observations

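Apart from the adjustment over all peaks, the tests in this part were chosen after the data were seen. URI peaks lay beside many regulator genes outside Fe homeostasis. Of 13 gene families taken by symbol, WRKY transcription factors were near a peak most often, 34 of 71 genes (47.9%) against 15.8% in genes matched on the space to their neighbours (adjusted permutation p = 0.0013). Heat shock factors (8 of 20, adjusted permutation p = 0.0078), ERF and DREB factors (15 of 49, 0.0338), JAZ repressors (5 of 12, 0.0367) and NAC factors (23 of 100, 0.0432) also passed, while the other 8 families did not. Closest to the threshold were genes with bHLH symbols (7 of 22, adjusted permutation p = 0.052, with 3 called peaks), calmodulin-like genes (5 of 14, 0.052) and auxin response genes (13 of 54, 0.0543). The bHLH set left out bHLH genes such as PYE, so it does not describe the whole family of URI. Farther away were bZIP (8 of 40, 0.207), homeobox (12 of 59, 0.302), LBD (7 of 40, 0.551), ribosomal protein symbols (5 of 59, 0.717) and MYB (17 of 125, 0.823). Membership by symbol was not checked against gene function, for example for RPS2 (AT4G26090) among the ribosomal protein symbols, so that share may not describe ribosomal protein genes. Of the highly expressed housekeeping genes, 38.9% were near a peak, and no family was tested against them. Signal at highly expressed or open genes in general thus stays open for these families too. The strongest WRKY peaks in the authors' deposited table lay at WRKY23, WRKY72, WRKY11 and WRKY17, with concentrations of 5.48, 5.43, 5.29 and 5.28. None of the 39 WRKY peaks had an FDR under 0.05 in the authors' deposited table, and their median log2 change of -0.57 lay close to the -0.46 of all peaks. Relative to the median peak, 2 of the 39 passed, WRKY12 (FDR 0.00443) and WRKY59 (FDR 0.0063), both higher under deficiency.

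Several peaks passed the threshold once changes were taken relative to the median peak. Among the 37 added were peaks nearest to FD2, the ferredoxin gene of the plastid list, with a relative log2 change of 1.64, NIA2 (nitrate reductase, 1.5) and SIR (sulfite reductase, 1.17), with FDR values of 0.00154, 0.0028 and 0.0119. A peak within AT5G22120 (chromosome 5, 7336336 to 7337100) went from 0.973 to 15 reads in the authors' deposited table (log2 change 3.95, p = 2.58e-06), the largest change there, but its FDR was set to 1 for low concentration. Adjusted over all peaks its FDR was 0.000407. Ranked by reads per kb, only 4 of the 10 peaks of highest concentration stayed among the first 10 (DGAT3, AT3G56360, FER1 and AT5G05250), and FER3, PYE and NAC047 did not. Another 4 of the 10 densest peaks had AT4G06688 (29742 and 30716 bp away), AT5G30520 (95370 bp away) or AT1G40104 as their nearest gene, with implied standard errors of 1.72 to 1.97 (log2), against a median of 0.346 among the strongest 10% of peaks.

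The first pattern is the lower URI signal under Fe deficiency at most peaks. Among peaks neither called nor near Fe genes, the median change was -0.47. The decile medians of concentration from the second upward deviated from it by at most 0.09, within the 0.15 (log2) allowed here for a single scaling factor between the conditions. The 95% bootstrap intervals of decile 6 (-0.6 to -0.5) and of the highest decile excluded -0.47, so 1 factor describes these medians only approximately. The lowest decile, at -0.115, departed from 1 factor, but its concentrations of 1.82 to 2.85 lie nearest the floor. How counts so low were treated is not known, so this value cannot decide. The -0.38 of the highest decile (95% bootstrap interval -0.43 to -0.31) argues against a selection of weak peaks as the whole cause. Lower binding at most sites under deficiency stays open as the biological explanation, because library totals and values per library were not used here, so it cannot be told apart from a scaling factor. If the offset is one of scaling, the recentred count of 63 higher peaks applies in place of 26.

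The second pattern is the large share of Fe genes near a peak. More space around these genes did not account for it: 35 of 58 had a peak, while the highest of 10000 sets matched on flanking space had 19 (permutation p = 0.0001, the smallest they can give). Signal at highly expressed or open genes could add to it, since 38.9% of housekeeping genes against 60.3% of Fe genes had a peak, a difference that Fisher's exact test did not resolve (two-sided p = 0.174). The IgG signal at these peaks was not analysed here, so this stays open beside URI binding itself.

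The third pattern is that ferritin peaks were among the strongest yet were not called higher. Their mean change was -0.63 ± 0.37 (SD over 3 peaks), against 1.33 ± 0.67 for 14 other strong Fe-list peaks (exact two-sided permutation p = 0.00147, over 680 combinations), but the groups were formed after the values were seen. One hypothesis, which this test on groups taken from the same values cannot settle, is that URI may gain under Fe deficiency at most other strong Fe-list peaks and not at ferritin genes. A ceiling on signal common to all peaks did not account for FER4, since DGAT3 lay 1.87 (log2) above it under deficiency, by more than 2 standard errors (0.619, an upper bound from the changes). For FER1 and FER3 it stays open: 5 other peaks were above them under deficiency, but DGAT3, the highest, only by 0.81 and 0.92 (log2), under 2 standard errors (0.679 and 0.682).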
